A study of Mus musculus with 14 samples.

How the data were processed

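Liver total RNA of 14 mice, 7 per diet, was hybridised as biotin-labelled cRNA to Affymetrix mouse arrays, 1 animal per array, per the labels' protocols. The values analysed were the deposited table of signal intensity per probe set, on a linear scale. Per the submitters' processing notes the intensity values were made with MAS5, the Affymetrix algorithm that summarises the probe pairs of a probe set and scales each array; its version is not given in the sources used here. In the deposited intensity table the mean of every array without the lowest and highest 2 percent of probe sets was the same, so arrays share a mean, and no normalization had equalised their distributions. Scanner files and detection calls are not used here, so no probe set could be marked as absent. A scaling of this kind raises every value on an array whose own RNA is dim, background included, which can lift low-signal genes.

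Groups and replicate numbers came from the sample titles. The table held 45101 probe sets, 64 of them controls. The platform table of probe sets and genes listed 34945 with 1 gene symbol and 932 with several, and 9160 not listed with a gene stay unnamed here. The gene number was found in the mouse gene table of assembly GRCm38.p6 for 34754 probe sets and 0 symbols needed an update; no coordinates are given, since no build is named for the array values. Probe sets with several genes or with no listed gene entered no test of genes or lists. After this and the signal filter described next, 39 of the 72 genes written in the ribosomal protein list were tested.

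Signal was transformed as log2(signal + 16), so folds of dim genes are understated. The 50% of probe sets with the higher mean over all arrays, 22518, were kept, and of these the probe set with the highest mean stood for each gene, which left 11308 genes. Diet was tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend) on all 14 arrays with no covariate, and p-values were adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. Log2 changes are krill minus control with the moderated standard error. Before the data were examined, 47 gene lists for pathways and liver cell types were fixed, and 41 with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 41. Camera asks whether a list moved more than other genes. It was repeated with the correlation estimated for each list, and fry, a rotation test of whether a list's genes move one way, was run as well. None of the 5 calls held with an estimated correlation.

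The rule for named genes was also fixed in advance. It takes the 12 largest rises and 12 largest falls among genes past the threshold, skipping unnamed transcripts, then up to 4 members per list with the smallest p, and a panel of 30 genes whatever their p. The genes named from lists that were not called are a selection from those the rule allows, made after their values were seen.

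Array quality was measured in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, from 18 hybridisation spike-in and 24 poly-A spike-in probe sets and from the 3' and 5' control probe sets; figures were drawn with matplotlib 3.10.9. The 3'/5' index is the mean log2 ratio of the actin and pyruvate carboxylase pairs and leaves out the third housekeeping pair. Group differences in these 7 measures were tested by exact permutation over 3432 assignments, two-sided.

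Alternatives set in advance were a pseudocount of 1 or 64, quantile normalization, centring on the array median, no signal filter or the upper 30%, every probe set or the mean of a gene's probe sets, no trend, array weights, the replicate number as a block, each array left out, and the other set tests. Alternatives chosen after seeing the data were the spike-in level or the 3'/5' index as a covariate, leaving out krill replicates 2, 4, 5 and 7, whose spike-in level lay above every control array, and scaling on the spike-ins. The splits of the 10 arrays that remain without those 4, the level of olfactory and vomeronasal receptors as a background and the changes with signal raised to it were also chosen after the data were seen. Tested on simulated data with 7 arrays per diet and 11308 genes, the procedure recovered 52 of 100 genes changed by 1 and 90 of 100 changed by 2 on the log2 scale, and called 8 of 11078 unchanged genes. The simulated genes varied independently of each other, with equal spread in both diets and no difference in array quality. These rates therefore do not carry over to the real arrays, whose quality differed between the diets.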

Results

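Liver RNA from 14 male CBA/J mice, an inbred laboratory strain, was measured on Affymetrix mouse expression arrays, with 1 mouse per array. The animals were kept singly on a fixed ration of 84 kcal per week of a purified maintenance diet. From 2 months of age, 7 mice received the control diet and 7 received a version holding an extract of krill, a marine crustacean rich in long-chain omega-3 fatty acids. Livers were taken at 5 months of age, after 3 months of feeding. The diets were matched for total protein and total lipid and differed in their amino acids and fatty acids. Each array reported 45101 probe sets as linear signal, and every array had been scaled to the same trimmed mean. The number of arrays limits the precision. Since each array holds a separate animal, the p-values refer to the spread between mice together with that between their arrays.

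The arrays of the diets also differed in technical measures. The ratio of signal from the 3' end to the 5' end of the actin transcript, which rises as RNA is shortened, was 2.09 ± 0.242 (SD, n = 7) in control and 2.98 ± 0.493 (SD, n = 7) in krill arrays. For pyruvate carboxylase the ratio was 6.55 ± 2.34 (SD, n = 7) in control and 18.3 ± 5.69 (SD, n = 7) in krill arrays. In both measures all 7 krill arrays lay above all 7 control arrays (exact permutation test, two-sided, p = 0.000583, the smallest that 3432 assignments can give, adjusted p = 0.00136 over 7 measures). The third housekeeping pair gave 0.806 ± 0.0496 (SD, n = 7) and 0.964 ± 0.33 (SD, n = 7), a difference that did not pass (exact permutation p = 0.198, adjusted p = 0.198). Hybridisation spike-ins, which are added in equal amounts and read brighter after scaling when an array's own RNA is dim, averaged 12.92 ± 0.22 (SD, n = 7) on the log2 scale in control and 13.71 ± 0.62 (SD, n = 7) in krill arrays (exact permutation p = 0.0128, adjusted p = 0.0179). Poly-A spike-ins, which are added to the RNA before labelling, averaged 10.87 ± 0.35 (SD, n = 7) in control and 11.997 ± 0.89 (SD, n = 7) in krill arrays (exact permutation p = 0.0122, adjusted p = 0.0179). In the hybridisation spike-ins krill replicates 2, 4, 5 and 7 stood at 14.21, 14.13, 14.12 and 14.34, above every control array, and krill replicates 1, 3 and 6 at 12.92, 13.17 and 13.09.

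**Figure D1:**
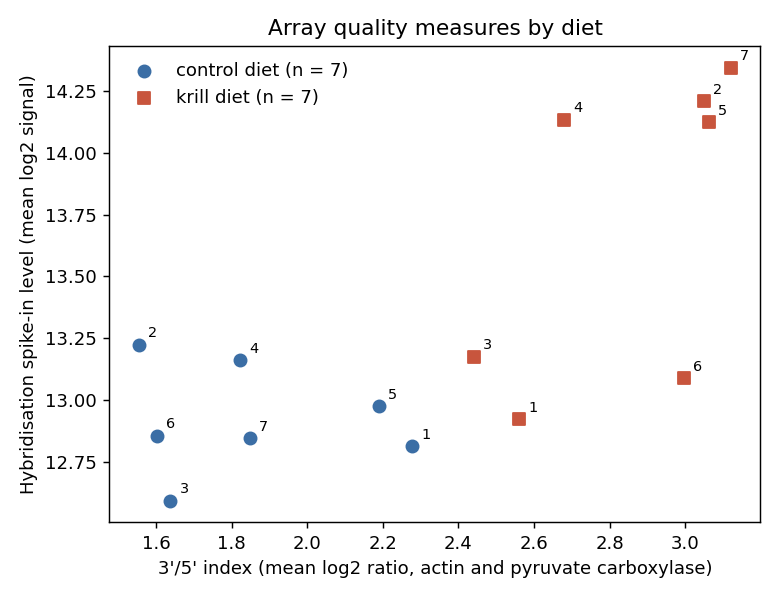
Hybridisation spike-in level (vertical axis, mean log2 signal) against the 3'/5' index (horizontal axis, mean log2 ratio of the actin and pyruvate carboxylase probe sets) for each of the 14 arrays, with replicate numbers beside the points. Blue circles are control and red squares krill arrays; the index runs from 1.56 to 2.28 in control and from 2.44 to 3.12 in krill arrays, and krill replicates 2, 4, 5 and 7 have spike-in levels of at least 14.12.

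The comparison of krill with control livers asked which transcripts differed after 3 months on the diets. Fads1 and Fads2, the desaturases of polyunsaturated fatty acid synthesis, were 4.44-fold and 4.29-fold lower on the krill diet, and Mlxipl and Srebf1, transcription factors of sugar-driven and insulin-driven fat synthesis, were 6.51-fold and 2.57-fold lower. Cpt1a, the entry step of mitochondrial fatty acid oxidation, was 3.62-fold lower and Pck1, a gluconeogenic enzyme, 4.07-fold lower. The log2 changes of Cpt1a and Pck1 were -1.86 and -2.02 with all arrays, and -1.04 and -1.11 without krill replicates 2, 4, 5 and 7. Transcripts of cytosolic ribosomal proteins and of the respiratory chain were mostly higher, with 26 of 39 and 38 of 71 tested members rising. Of the circadian clock genes 9 of 15 fell, of the periportal hepatocyte markers 6 of 7 and of the genes of sterol uptake and regulation 7 of 15. The calls of these lists and of the ribosomal and respiratory lists were lost with an estimated correlation (adjusted p = 0.713). In all, 5397 of 11308 tested genes (47.7%) changed (limma, Benjamini-Hochberg adjusted p under 0.05), 2594 higher and 2803 lower, and 2588 of them by at least 2-fold.

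The fatty acid synthesis and desaturation list had 22 tested members, of which 3 rose, 8 fell and 11 did not pass; adjusted over the list alone the counts were 3 and 8. Fads1 had a signal of 14583 ± 3420 (SD, n = 7) in control and 3814 ± 2272 (SD, n = 7) in krill livers, a log2 change of -2.15 (SE 0.34, limma adjusted p = 9.55e-05). Fads2 went from 13473 ± 2350 (SD, n = 7) to 3408 ± 1593 (SD, n = 7), a log2 change of -2.10 (SE 0.25, limma adjusted p = 2.13e-05). For both genes all 7 krill arrays lay below all 7 control arrays, and 4 of their 5 probe sets past the filter were called lower, the exception being a Fads1 probe set at -0.20 (limma adjusted p = 0.502). Mlxipl changed by -2.70 (SE 0.28), Srebf1 by -1.36 (SE 0.25) and Fasn, the fatty acid synthase, by -1.12 (SE 0.34). Scd1, the stearoyl-CoA desaturase, was called higher at 0.60 (SE 0.21), but its probe sets were called in both directions. Its sign turned to -1.22 for the mean of its probe sets, where it was called lower, to -0.20 with quantile normalization, to -0.05 with the spike-in level in the model and to -0.19 with spike-in scaling. Without krill replicates 2, 4, 5 and 7 Scd1 stood at 0.07 and no longer passed (limma adjusted p = 0.781). Elovl6, an elongase, changed by -0.63 (limma adjusted p = 0.125). The list as a whole had a median log2 change of -0.48 and was not called (camera adjusted p = 0.0644, and adjusted p = 0.713 with an estimated correlation). Without krill replicates 2, 4, 5 and 7 its median was -0.34. It was called in 11 of the 29 alternative fits (camera adjusted p from 0.00149 to 0.161).

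**Figure D2:**
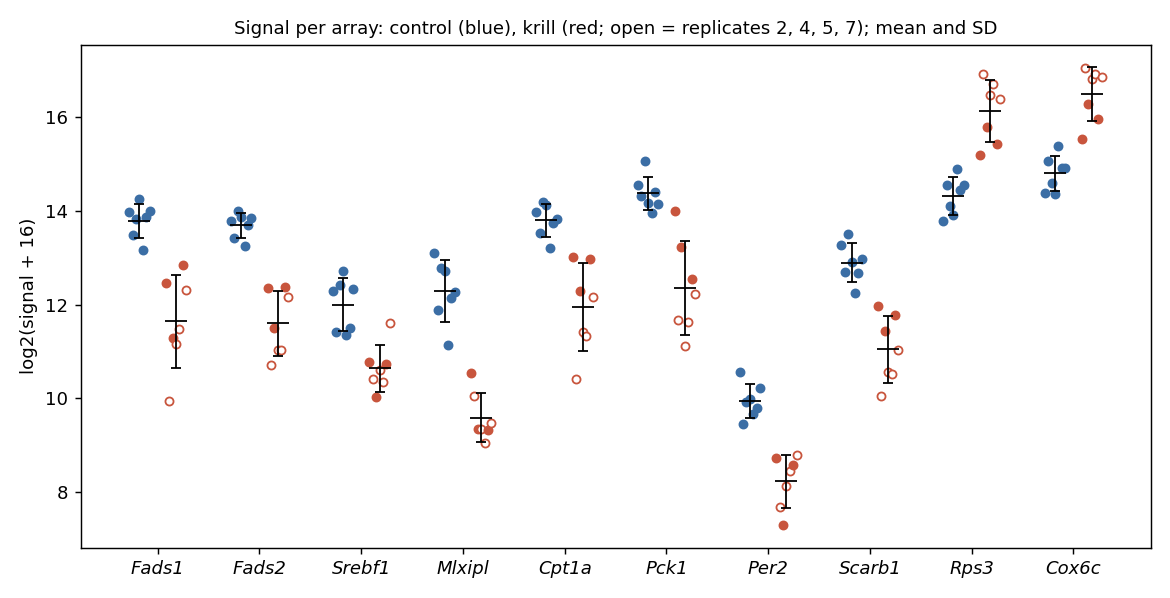
Signal of 10 genes on each array (vertical axis, log2 of signal plus 16), control arrays in blue and krill arrays in red, with the mean and SD of each group of 7 as bars. Open red symbols are krill replicates 2, 4, 5 and 7; in Fads1, Fads2, Mlxipl, Cpt1a, Per2 and Scarb1 every krill array lies below every control array, and in Rps3 and Cox6c every krill array lies above.

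Of 18 tested genes of triglyceride synthesis and lipid droplets, 3 rose, 7 fell and 8 did not pass (3 and 7 adjusted over the list alone). The adipose triglyceride lipase Pnpla2 changed by -2.06 (SE 0.21), Cideb, a protein of lipid droplets and lipoprotein loading, by -2.98 (SE 0.37), Dgat2, a last-step enzyme of triglyceride synthesis, by -1.69 (SE 0.30) and the hormone-sensitive lipase Lipe by -1.43 (SE 0.22). Plin2, a lipid droplet coat protein, fell by 0.67 on the log2 scale. In mitochondrial fatty acid oxidation 4 of 19 tested members rose, 12 fell and 3 did not pass (5 and 12 adjusted over the list alone), among them Cpt1a at -1.86 (SE 0.32), the acyl-CoA dehydrogenase Acadl at -1.08 (SE 0.18) and the enoyl-CoA isomerase Eci2 at -1.44 (SE 0.27). The medians of these lists were -0.18 and -0.68, neither was called (camera adjusted p = 0.216 and 0.215), and without krill replicates 2, 4, 5 and 7 they were -0.17 and -0.06. Each of these lists was called in 2 of the 29 alternative fits. Without those arrays Cideb stood at -1.93, Dgat2 at -0.88 and Cpt1a at -1.04, and Plin2 stood at -0.37 and no longer passed (limma adjusted p = 0.136). Among PPAR alpha targets and ketogenesis genes 2 of 16 rose and 4 fell (2 and 4 adjusted over the list alone). Ppara itself, the fatty acid sensor, changed by -1.93 (SE 0.28), and by -1.18 without those arrays. Of the list's other members Fabp2 and Fabp1, fatty acid binding proteins, changed by 1.57 (SE 0.24) and 0.80 (SE 0.21), and the thioesterase Acot2 by -1.25 (SE 0.28). Fabp1 stood at 0.28 without those arrays and no longer passed. Of the targets fixed in advance in the panel, some of them outside this list, Cyp4a14, Ehhadh, Pdk4, Fgf21 and Cd36 had log2 changes of -0.28, 0.07, 0.36, -0.08 and -0.19 and did not pass (limma adjusted p from 0.446 to 0.87). Cd36 stood at 0.74 without krill replicates 2, 4, 5 and 7.

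Among 17 tested cholesterol biosynthesis genes 2 rose, 4 fell and 11 did not pass (2 and 4 adjusted over the list alone). Idi1, the isopentenyl diphosphate isomerase, changed by 1.20 (SE 0.31), Dhcr7 by -0.88 (SE 0.29) and Ebp by -0.56 (SE 0.16), and Cyp51 by 0.76 (SE 0.21), although with spike-in scaling Cyp51 stood at -0.01. Squalene epoxidase, Sqle, changed by -0.47 (limma adjusted p = 0.455), and by 0.46 without krill replicates 2, 4, 5 and 7, where Ebp stood at -0.24 and no longer passed (limma adjusted p = 0.213). The list median was 0.02, its mean -0.04 and its camera direction down (adjusted p = 0.901). Sterol uptake and regulation was called lower (camera adjusted p = 0.028, median -0.49, 7 of 7 krill arrays below the control mean), with 1 of 15 members higher, 7 lower and 7 not passing (1 and 7 adjusted over the list alone). With an estimated correlation its adjusted p = 0.713. The members with the smallest p were the sterol exporter Abcg8 at -1.69 (SE 0.20), the SREBP escort protein Scap at -1.78 (SE 0.23), the lysosomal cholesterol transporter Npc1 at -2.38 (SE 0.33) and the HDL receptor Scarb1 at -1.85 (SE 0.27). Without krill replicates 2, 4, 5 and 7 Scarb1 stood at -1.17, the list's median was -0.40 and its call ended, as it also did under 5 other alternatives (camera adjusted p = 0.133, with a range of 0.00032 to 0.183 over the 29 alternative fits). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, changed by 0.53 (limma adjusted p = 0.118), and by 1.00 without those arrays, where it passed (limma adjusted p = 0.0168). Apoa4, an apolipoprotein, was called higher at 0.76 (SE 0.24), but stood at 0.22 without those arrays and no longer passed (limma adjusted p = 0.472), with a sign that turned to -0.03 under spike-in scaling and to -0.08 with the 3'/5' index in the model.

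Cytosolic ribosomal proteins were called higher (camera adjusted p = 2.06e-05, 7 of 7 krill arrays above the control mean), with 26 of 39 tested members higher, 3 lower and 10 not passing (27 and 3 adjusted over the list alone) and a median log2 change of 0.85, which was 0.41 with quantile normalization and 0.06 with spike-in scaling. With an estimated correlation the adjusted p = 0.713. Rps3, Rps14, Rpl13a and Rps7 changed by 1.81 (SE 0.26), 1.73 (SE 0.25), 1.70 (SE 0.25) and 1.58 (SE 0.23). Oxidative phosphorylation was called higher too (camera adjusted p = 0.000228, 7 of 7 krill arrays above the control mean), with 38 of 71 members higher, 12 lower and 21 not passing (39 and 14 adjusted over the list alone). Its median was 0.62, which turned to -0.17 under spike-in scaling, where the median of all genes was -0.72. With quantile normalization its median was 0.12, against 0.05 for all genes, and its call ended (camera adjusted p = 0.0786, with a range of 2.69e-08 to 0.0786 over the 29 alternative fits), and with an estimated correlation the adjusted p = 0.713. Cox6c, Atp5l, Atp5k and Ndufb11, subunits of cytochrome oxidase, ATP synthase and complex I, changed by 1.68 (SE 0.24), 1.81 (SE 0.26), 1.52 (SE 0.23) and 1.53 (SE 0.23). Without krill replicates 2, 4, 5 and 7 the medians of the ribosomal and respiratory lists were 0.54 and 0.47. In the same fit Rps3, Rps14, Rpl13a and Rps7 stood at 1.15, 1.07, 1.06 and 0.98. In the proteasome list 11 of 31 members rose, 4 fell and 16 did not pass (11 and 4 adjusted over the list alone), led by Psma7 at 2.21 (SE 0.28) and Psmb3 at 1.77 (SE 0.23), and the list was not called (camera adjusted p = 0.0828). Its median of 0.19 was 0.44 without krill replicates 2, 4, 5 and 7, 0.48 with the spike-in level and 0.64 with the 3'/5' index in the model. It was called higher in these fits (camera adjusted p = 9.92e-07, 5.13e-07 and 4.22e-07, with a range of 4.22e-07 to 0.212 over the 29 alternative fits). With an estimated correlation and all arrays its adjusted p = 0.713. The median turned to -0.21 with arrays centred on their medians and to -0.59 with spike-in scaling. Relative to all genes it was 0.15 as deposited, 0.15 with centring and 0.12 with spike-in scaling. Psma7 stood at 1.48 without those arrays.

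The circadian clock list was called lower (camera adjusted p = 0.0263, median -0.96, 7 of 7 krill arrays below the control mean), with 1 of 15 tested members higher, 9 lower and 5 not passing (1 and 9 adjusted over the list alone). With an estimated correlation its adjusted p = 0.713. The period genes Per2 and Per3 changed by -1.71 (SE 0.24) and -1.48 (SE 0.29), the repressors Nfil3 and Bhlhe40 by -1.97 (SE 0.33) and -1.74 (SE 0.30), and the output factor Dbp by -0.85 (SE 0.30). The time of day at which livers were taken, on which clock transcripts depend, is not given in the sources used here. Without krill replicates 2, 4, 5 and 7 Nfil3 stood at -1.04, Dbp, at -0.93, no longer passed (limma adjusted p = 0.101) and the list's median was -0.92, which was -0.92 with the 3'/5' index in the model. The call ended in the upper 30% of signal and with spike-in scaling (camera adjusted p = 0.0695 and 0.0688, with a range of 0.000151 to 0.0695 over the 29 alternative fits).

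Periportal hepatocyte markers, genes of liver cells near the incoming blood, were called lower (camera adjusted p = 0.00873, median -1.41, 7 of 7 krill arrays below the control mean), with 0 of 7 members higher, 6 lower and 1 not passing (0 and 6 adjusted over the list alone). With an estimated correlation the adjusted p = 0.713. Of the 7 members 4 stand in other lists too. Hsd17b13, a lipid droplet protein, changed by -1.81 (SE 0.25), the histidine ammonia-lyase Hal by -1.41 (SE 0.22), Pck1 by -2.02 (SE 0.34) and Cyp2f2 by -1.59 (SE 0.35). Hsd17b13 stood at -1.18, Pck1 at -1.11 and Cyp2f2 at -0.50 without krill replicates 2, 4, 5 and 7. With the 3'/5' index in the model the list's median was -0.86 and its call ended, as it did with spike-in scaling (camera adjusted p = 0.13 and 0.08, with a range of 0.000151 to 0.13 over the 29 alternative fits). Of the markers of the opposite, pericentral zone 1 of 10 rose, 4 fell and 5 did not pass (1 and 4 adjusted over the list alone), with a median of -0.68 and 7 of 7 krill arrays below the control mean (camera adjusted p = 0.0828, with a range of 0.00365 to 0.577 over the 29 alternative fits; fry adjusted p = 0.000374). That list was not called, was called in 3 of the 29 alternative fits, and had an adjusted p = 0.713 with an estimated correlation. In glycolysis and glycogen 2 of 16 members rose, 9 fell and 5 did not pass (2 and 9 adjusted over the list alone). Phosphofructokinase Pfkl changed by -2.01 (SE 0.30), pyruvate kinase Pklr by -1.26 (SE 0.20), glycogen synthase Gys2 by -1.67 (SE 0.29) and fructokinase Khk by 1.37 (SE 0.23). In gluconeogenesis 1 of 13 rose and 6 fell (1 and 7 adjusted over the list alone), G6pc among them at -0.62 (SE 0.25). In urea cycle and amino acid catabolism 5 of 33 rose and 16 fell (5 and 17 adjusted over the list alone), with Aldh4a1, of proline breakdown, at -2.24 (SE 0.29) and Gstz1, of tyrosine breakdown, at 0.97 (SE 0.16). None of these 3 lists was called (camera adjusted p = 0.0604, 0.131 and 0.0604), and without krill replicates 2, 4, 5 and 7 their medians were -0.52, -0.37 and -0.14. Without those arrays Pfkl stood at -1.35, Gys2 at -0.76 and Aldh4a1 at -1.48, and G6pc stood at -0.42 and no longer passed (limma adjusted p = 0.269). The lists were called in 10, 2 and 11 of the 29 alternative fits, quantile normalization among them.

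**Figure D3:**
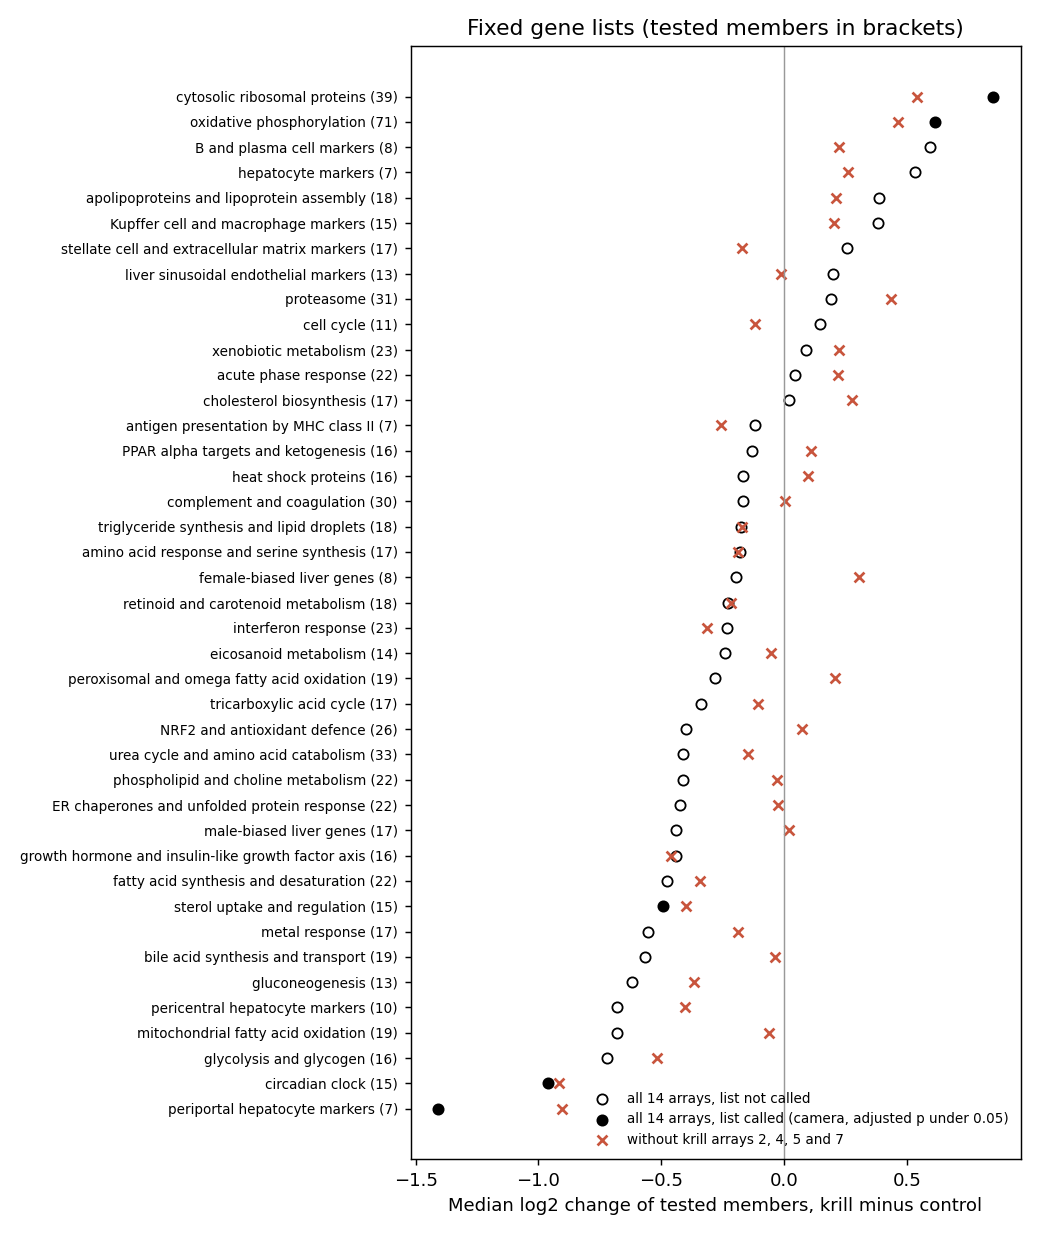
Median log2 change of the tested members of each of the 41 gene lists (horizontal axis, krill minus control), with the number of tested members in brackets. Filled circles are the 5 lists called with all 14 arrays, open circles the others, and red crosses the medians without krill replicates 2, 4, 5 and 7; the ribosomal list moves from 0.85 to 0.54 and the periportal list from -1.41 to -0.90.

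The largest falls were in Reep6, a membrane-shaping protein, at -6.10 (SE 0.71), the transcription factors Nfic and Nfix at -4.56 (SE 0.48) and -4.43 (SE 0.50), the male-biased fatty acid hydroxylase Cyp4a12a at -4.34 (SE 0.46), the mitochondrial carrier Slc25a23 at -4.26 (SE 0.46), the nuclear RNA Neat1 at -4.17 (SE 0.60), the aminopeptidase Anpep at -4.04 (SE 0.47) and Sema4g at -3.85 (SE 0.35). The glutathione transferase Gstm1, the Krebs cycle enzyme Ogdh, the chaperone Bag6 and the RNA export factor Nxf1 changed by -3.73, -3.64, -3.64 and -3.58. In all 12 genes every krill array lay below every control array, and Neat1 had probe sets called in both directions. The sizes and order of most of these falls, and of most of the rises that follow, are limited by background. The largest rises were in Mtm1, a phosphoinositide phosphatase, at 3.40 (SE 0.57), Zfp982 at 3.20 (SE 0.60), Ifnz at 2.83 (SE 0.61), Smyd5 at 2.81 (SE 0.48), Zfp980 at 2.77 (SE 0.67) and Ntmt1 at 2.71 (SE 0.55). Vmn1r148, Speer8-ps1, Pet100, Astx3, Pcdh10 and Mtln followed at 2.60, 2.59, 2.59, 2.51, 2.49 and 2.49. Several of the risers had low signal in control livers, such as 62.9 ± 33.9 (SD, n = 7) for the vomeronasal receptor Vmn1r148. Over 78 olfactory and vomeronasal receptor probe sets, genes of sensory neurons, the median signal was 30.8 ± 5.64 (SD, n = 7) in control and 107 ± 58.7 (SD, n = 7) in krill arrays (exact permutation p = 0.00233), with krill replicates 2, 4, 5 and 7 at 131 or above krill replicate 3 at 71.1, krill replicate 6 at 38.9, close to the highest control array at 38.0, and krill replicate 1 at 32.4, within the control range. Signal lay under this receptor median in 6 of 7 krill arrays for Nfic and Nxf1, in 5 for Bag6, in 4 for Nfix, Neat1 and Anpep, in 3 for Ogdh and in 2 for Reep6 and Slc25a23. With every array's signal raised to at least its own receptor median the changes were -3.28 for Nfic, -2.32 for Nxf1, -2.07 for Bag6, -3.64 for Nfix, -3.05 for Neat1, -3.18 for Anpep, -3.09 for Ogdh, -5.49 for Reep6 and -3.88 for Slc25a23. Among the risers, control signal lay under the receptor median in 3 of 7 arrays for Ifnz, Zfp980 and Pcdh10, in 2 for Zfp982, Vmn1r148 and Speer8-ps1 and in 1 for Smyd5 and Astx3. Raised in the same way, the changes were 2.58 for Ifnz, 2.40 for Zfp980, 2.22 for Pcdh10, 3.08 for Zfp982, 2.47 for Vmn1r148, 2.44 for Speer8-ps1, 2.73 for Smyd5 and 2.40 for Astx3. Raising alters only values under the level and removes no background from krill signal above it. The receptor median itself was higher in krill arrays by 1.56 on the log2 scale. These values therefore do not show whether the rises go beyond background. Of the 2803 genes called lower, 911 had at least 1 krill array under this level and 207 had 4 or more. When krill replicates 2, 4, 5 and 7 were left out, Mtm1 stood at 1.62, Reep6 at -4.31, Nfix at -3.40, Cyp4a12a at -3.02, Slc25a23 at -3.65, Neat1 at -2.50, Gstm1 at -2.81 and Ogdh at -2.53. All 12 risers moved by over 1.5-fold. Ifnz, Zfp980, Speer8-ps1 and Astx3 then no longer passed. Smyd5 stood at -0.73 under spike-in scaling, where the probe set of each gene was chosen anew. Spike-in levels differed by only 0.79 between the diets, so this value came from another Smyd5 probe set than the rise of 2.81.

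Of the 41 lists 5 were called, a number that 62 of 100 splits of the arrays reached or passed, and 8 were called without control replicate 1, control replicate 2 or krill replicate 6. Of the 30 genes fixed in advance as a panel, 22 were tested, 3 rose, 11 fell, 1 lay under the signal filter and 7 are not used here. Beside those above, the panel held the acute phase protein Saa1, at 1.60 (SE 0.44), and the metallothionein Mt1, at -1.40 (SE 0.38). They stood at 2.40 and -0.30 without krill replicates 2, 4, 5 and 7, and Mt1 turned to 0.60 with the 3'/5' index in the model.

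Without krill replicates 2, 4, 5 and 7, an exclusion chosen after seeing the data, 3651 genes were called, 1438 higher and 2213 lower, and 3068 of the 5397 genes kept both call and direction; with the 3'/5' index in the model 0 genes were called by limma, against 1873 at an unadjusted p under 0.05. Of the calls, 48.1% were higher as deposited, 21.2% with arrays centred on their medians and 5.63% with spike-in scaling, which moved the median change of all genes from 0.04 to -0.36 and -0.72. In 1598 genes the groups did not overlap, against a chance share of 0.0583% of genes.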

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

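Of the tests below, those that leave out krill replicates 2, 4, 5 and 7, the covariate test of Fads1 and Fads2 and the count of random splits for gene lists were chosen only after the results were seen.

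In 246 groups of 7 arrays checked for a single array far from the rest, 8 were marked, where chance marks about 5%. Reep6 had a log2 signal of 12.75 in control replicate 5, against 13.98 to 14.82 in the other control arrays, and Cideb 12.17 in the same array, against 13.03 to 13.63. Nxf1 stood at 8.11 in krill replicate 1, against 5.20 to 5.68 in the other krill arrays. Fgf21 stood at 6.56 in krill replicate 7, below the other krill arrays, which reached 8.82, and Dbp at 10.51 in krill replicate 3, against 11.64 to 12.45. Lum, a matrix protein, stood at 11.54 in krill replicate 2, against 10.06 to 10.47. Jchain, of plasma cells, stood at 8.80 in control replicate 2, against 7.72 to 8.04 in the other control arrays, and Lyve1, of endothelium, at 7.65 in control replicate 3, against 8.37 to 8.87.

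The breadth of the difference, 5397 of 11308 genes, is the first pattern. In 100 splits of the 14 arrays into 7 and 7, only the real one (1 split) called as many genes. The highest other called 3647, with 6 krill arrays and all 4 of replicates 2, 4, 5 and 7 on one side. Chance is thus an unlikely source, as far as 100 splits can tell. The dimness of sample RNA relative to the spike-ins in those 4 arrays is not the whole source, because 3651 genes were called without them. Of all 120 splits of the remaining 10 arrays into 3 and 7 only the real one (1 split) called as many, the highest other calling 1890 (exact permutation, one-sided, p = 0.00833). Krill replicate 3, which stayed in, had a receptor median of 71.1 and a median signal of 125.8, against at most 38.0 and 109.5 in control arrays. The receptor median of krill replicate 1, at 32.4, lay within the control range. The exclusion therefore does not decide whether a lesser dimness of the remaining krill arrays contributed. Lower RNA integrity, as measured by the 3'/5' index, cannot be told apart from the diet, since 78.5% of the variance of the index lies between the diets. The index holds the actin and pyruvate carboxylase pairs and leaves out the third housekeeping pair, whose difference did not pass. Within the krill arrays the slope of each gene on the index correlated with its diet change at r = 0.521 across genes, which are not independent replicates (exact permutation, one-sided, p = 0.164, and r = 0.02 with p = 0.47 in control arrays). With the index in the model the median standard error rose from 0.24 to 0.50 and the median change of the 5397 genes, in the direction of their call, went from 0.98 to 0.68, with 565 of them of opposite sign, so the calls ended through both wider errors and smaller changes, and an effect of diet stays open as well.

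The second pattern is the higher ribosomal protein and respiratory chain lists. With the arrays as deposited, the dimness of 4 krill arrays is not the whole source, since without them the medians were 0.54 and 0.47. Medians as high came in 1 and 2 of the 120 splits of the remaining 10 arrays (exact permutation, one-sided, p = 0.00833 and 0.0167). These p-values refer to the grouping of the arrays, not to dimness. Both lists were picked for their rise with all arrays, these 10 included, and the p-values are not adjusted for that choice. Krill replicate 3, with its raised receptor median, stayed in, so a lesser dimness is not excluded. At the preset correlation of 0.01 camera called both lists with the arrays as deposited, but the respiratory call ended with quantile normalization (camera adjusted p = 0.0786). In that setting the respiratory median stood 0.066 above that of all genes and the ribosomal median 0.36 above it. Both calls were lost with an estimated correlation (camera adjusted p = 0.713 with all arrays). Lower RNA integrity stays open: the median slope of the 110 members on the index within the diets, minus that of all genes, was -0.064 (permutation p = 0.626 for a value that high and 0.374 for one that low), which decides nothing. For the number of called lists chance cannot be excluded, because 62 of 100 splits called as many as the real 5 and the highest other called 20.

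The third pattern is the lower Fads1 and Fads2. Their mean log2 change was -2.13 (SE 0.33), and -1.96 (SE 0.75) with the 3'/5' index in the model, 2.61 standard errors below 0. In that fit 0 genes passed adjustment (limma, lowest adjusted p = 0.103), and 78.5% of the index variance lay between the diets. The value therefore argues only weakly against RNA integrity, as measured by that index, as the whole source. Without krill replicates 2, 4, 5 and 7 the mean change was -1.61 (SE 0.29), which argues against the dimness of those arrays as the whole source. Krill replicate 3, with its raised receptor median, stayed in, so a lesser dimness is not excluded. An effect of the diet, which differed in fatty acids, is a hypothesis that may account for the change, found and tested on the same arrays, and a batch that labels do not give was not tested.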

How the results depend on the processing

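The covariates, the spike-in scaling and the exclusion of krill replicates 2, 4, 5 and 7 were chosen after seeing the data; the other alternatives were planned. The cause of each change below was not tested unless stated. The number of changed genes, 5397, was 8729 (5055 lower) when every probe set was tested, because more features enter, 1978 (790 higher, 1188 lower) with the spike-in level as a covariate and 0 (0 higher, 0 lower) with the 3'/5' index. Higher genes, 2594, were 1001 with arrays centred on their medians, 1438 without krill replicates 2, 4, 5 and 7 and 327 with spike-in scaling, where 5483 were lower. Leaving out each array gave 4680 to 6147 changed, 2206 to 3125 higher and 2428 to 3022 lower genes and 5 to 8 lists, with 8 lists without control replicate 1, control replicate 2 or krill replicate 6. The 5 called lists became 16 with quantile normalization, 23 without a filter, 3 in the upper 30% of signal, 14 with every probe set, 9 with array weights, 2 with spike-in scaling, 0 with an estimated correlation (lowest adjusted p = 0.713) and 22 with fry. With the replicate block there were 8 lists and 5253 genes. Of 7 same-numbered pairs 0 had deviations correlated above 0.1 (-0.02 to 0.10) and 1 of 7 control arrays matched its own number best. The numbers thus gave no sign of a pairing of the mice, which the labels do not state. The ribosomal list was called higher in 29 of 29 alternative fits, with medians from 0.061 to 0.95. The signs turned for Scd1 with quantile normalization (-0.20), the mean of probe sets (-1.22), the spike-in covariate (-0.053) and spike-in scaling (-0.19), for Fabp1 with quantile normalization (-0.0092) and for Alb with quantile normalization (-0.15) and spike-in scaling (-0.26). With the 3'/5' index they turned for Apoa4 (-0.085), Mt1 (0.60), Lyve1 (-0.12), Serpina3n (0.062) and the heat shock list (0.43). With spike-in scaling they turned for Apoa4 (-0.030), Cyp51 (-0.014), Jchain (-0.026) and the respiratory list (-0.17). Smyd5 stood at -0.73 in that fit, but from another probe set. Without krill replicates 2, 4, 5 and 7 the fold change of 47 of the 118 genes named moved by over 1.5-fold. A further 91 sign changes concerned lists called in neither fit. Dim genes are limited by the raised floor of krill replicates 2, 3, 4, 5 and 7: in the lowest of 3 signal classes 848 genes rose and 497 fell.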

Other observations

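Of 15 tested Kupffer cell and macrophage markers 6 rose, 3 fell and 6 did not pass (6 and 3 adjusted over the list alone, camera adjusted p = 0.216, fry adjusted p = 0.0462, higher). Among those that rose were Cd5l at 1.18 (SE 0.20), Lyz2 at 1.11 (SE 0.22) and Adgre1 at 0.92 (SE 0.22), and the 3 that fell changed by -0.53 to -0.89. The markers thus did not move as 1 group. The list's median of 0.38 turned to -0.02 with arrays centred on their medians and to -0.34 with spike-in scaling. Both settings moved the median of all genes down. Relative to it the list stood at 0.34 as deposited, 0.34 with centring and 0.38 with spike-in scaling. Of 8 B and plasma cell markers 3 rose, 1 fell and 4 did not pass (4 and 1 adjusted over the list alone; camera adjusted p = 0.284, fry adjusted p = 0.0462, higher), Ms4a1 at 1.09 (SE 0.28), Jchain at 0.72 (SE 0.23), Mzb1 at 0.84 (SE 0.30) and Blnk at -1.04 (SE 0.25). The list's median of 0.60 was 0.22 without krill replicates 2, 4, 5 and 7, where Ms4a1, Jchain and Mzb1 no longer passed, and -0.16 with spike-in scaling. Relative to all genes it was 0.55 both as deposited and with spike-in scaling. Cd74, the invariant chain of MHC class II, changed by -1.40 (SE 0.23). In its list of MHC class II antigen presentation 1 of 7 tested members rose, 2 fell and 4 did not pass (1 and 2 adjusted over the list alone). That list was not called (camera adjusted p = 0.691). Of 13 sinusoidal endothelial markers 2 rose and 2 fell (2 and 2 adjusted over the list alone), Dnase1l3 at -1.98 (SE 0.27), the hyaluronan receptor Stab2 at -0.90 (SE 0.17), Lyve1 at 1.06 (SE 0.28) and Gpr182 at 0.86 (SE 0.23), with a median of 0.20. Lyve1 and Gpr182 stood at 0.48 and 0.45 without krill replicates 2, 4, 5 and 7 and no longer passed. Of 17 stellate cell and matrix markers 3 rose and 5 fell (3 and 5 adjusted over the list alone), with Ecm1 at -1.55 (SE 0.22) and Lum at 0.96 (SE 0.21); the median was 0.26 and the mean -0.04. Hepatocyte markers had 4 of 7 higher and 0 lower (4 and 0 adjusted over the list alone; camera adjusted p = 0.298, fry adjusted p = 0.0462, higher), Ttr at 0.86 (SE 0.21) and Alb at 0.53 (SE 0.19), with a median of 0.53 that turned to -0.15 with quantile normalization and -0.26 with spike-in scaling. Relative to all genes the hepatocyte list stood at 0.49 as deposited, -0.20 with quantile normalization and 0.46 with spike-in scaling. Ttr and Alb stood at 0.33 and 0.37 without krill replicates 2, 4, 5 and 7 and no longer passed (limma adjusted p = 0.145 and 0.124). Of the pericentral markers 1 of 10 rose and 4 fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.0828, fry adjusted p = 0.000374, lower), Cyp1a2 among them at -2.17 (SE 0.32), and at -1.31 without krill replicates 2, 4, 5 and 7. In 6 lists with fewer than 5 tested members, S100a8 of neutrophils, Tspan8 of bile ducts, Fabp2 and Cela1 of gut or pancreas and Ckm of muscle rose by 1.42, 1.29, 1.57, 1.31 and 1.08. The other tested members of these lists did not pass. Tspan8 and Ckm stood at 0.54 and 0.33 without krill replicates 2, 4, 5 and 7 and no longer passed.

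The acute phase list split, with 3 of 22 higher and 5 lower (3 and 5 adjusted over the list alone). Saa3 changed by 1.66 (SE 0.27), Lbp by -1.86 (SE 0.26) and Serpina3n by -1.97 (SE 0.42). Lbp stood at -1.15 and Serpina3n at -0.77 without krill replicates 2, 4, 5 and 7, and Serpina3n turned to 0.06 with the 3'/5' index in the model. In complement and coagulation 6 of 30 rose and 13 fell (6 and 13 adjusted over the list alone). The mannose-binding lectin Mbl1, among those that rose, changed by 1.70 (SE 0.21), and the 13 that fell changed by -0.40 to -2.14. In phospholipid and choline metabolism 3 of 22 rose and 9 fell (3 and 9 adjusted over the list alone). The choline oxidation enzymes Chdh and Sardh changed by -1.76 (SE 0.27) and -1.85 (SE 0.27), Sardh standing at -1.24 without those arrays, and Gnmt and the phosphatidylcholine enzyme Chpt1 by 1.07 (SE 0.19) and 0.89 (SE 0.17). In xenobiotic metabolism 7 of 23 rose and 8 fell (7 and 8 adjusted over the list alone), with the conjugating enzymes Sult1d1 at 1.65 (SE 0.26) and Ugt2b1 at 1.15 (SE 0.18). The acute phase, complement, phospholipid and xenobiotic lists were not called (camera adjusted p = 0.972, 0.286, 0.216 and 0.926). Over all tested genes 22.9% rose and 24.8% fell.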
